A study of Mus musculus with 40 samples.

How the data were processed

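The series holds ChIP-seq of mouse prostate organoids with antibodies against AR (PG-21, per the labels), FOXA1 and H3K4me2, in control and SPOP-mutant organoids treated for 24 h with 10 nM DHT or with EtOH. Of its 40 samples, 20 are ChIP libraries with 1 peak list each, in 10 groups of 2. The other 20 are inputs, which were not used here. Groups and replicate numbers were taken from the sample titles. The per-peak values belong to lists that were made per sample and not from pooled replicates.

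Libraries were made with the NEBNext Ultra II DNA kit, per the labels' protocols. Coordinates are on build mm10, per the submitters' processing notes. The aligner, the peak caller, the use of the inputs and any filters are not given in the sources used here. The AR and H3K4me2 lists and the mutant FOXA1 lists have the 10 columns of the narrowPeak layout, and the control FOXA1 lists have 3 (chromosome, start and end). In the narrowPeak lists the authors deposited a −log10 p-value and a −log10 q-value for each peak, with a lowest −log10 p of about 2.0 in every list. The deposited fold enrichment of each peak is taken as the signal over background of that layout, and the deposited score is the −log10 p on a scale of whole numbers, as the values show. These values are the authors' own for each peak and were used only to describe, rank or filter peaks within a list. No list gives reads, so depth was unknown and no value could be scaled to it.

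The gene table held 21887 protein-coding genes of assembly GRCm38.p6, the assembly that mm10 corresponds to, with start and end but no strand or exons. Distances were therefore taken to the gene span and to its nearer end instead of to a transcription start, and exons and introns were not told apart. No genome sequence was used here, so the planned motif comparison was not run.

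All peaks on chromosomes 1 to 19, X and Y were kept as deposited. Peaks of all libraries of an antibody that overlapped or touched were merged into regions, and a library held a region if at least 1 bp of a peak lay in it. A region was called mutant-only, control-only, DHT-only or EtOH-only if every library of that side and none of the other held it. For FOXA1 and H3K4me2 the larger of both counts was set against the same count in each of the 35 splits of the 8 libraries into 4 and 4, which is a two-sided test since each split and its mirror are counted together. The 4 AR libraries make 3 splits, too few for a test. Peak number, covered bases and the share of peaks near genes were compared by two-sided exact permutation tests over the 70 arrangements of 4 against 4 libraries, whose smallest p is 0.0286. Peak numbers were compared on the log2 scale. Similarity of libraries was the Jaccard index of covered bases. Its excess within over between groups was largest for the real split by genotype for FOXA1 (0.0877) and H3K4me2 (0.0621), in 1 of 35 splits each. By DHT it was 0.0470 for FOXA1 (2 of 35) and 0.0052 for H3K4me2 (16 of 35), and by genotype it was 0.0867 for AR (1 of 3). Shares of regions carry 95% Wilson intervals. Overlap expected by position was taken from the same peaks shifted by 100000 bp.

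A region was assigned to the protein-coding gene with the nearest span within 50 kb of its centre. There were 15 gene lists: androgen targets, luminal, basal, luminal progenitor, neuroendocrine, stromal, and endothelial and immune markers, SPOP substrates and BET proteins, the PI3K and mTOR pathway, the Wnt pathway, AP-1 and stress genes, steroid and lipid metabolism, cell cycle, housekeeping genes, and genes of other lineages. For each list the difference between first-only and second-only regions, as a share of the list's regions, was set against 100000 random lists matched on the number of regions per gene in 20 bins. The two-sided permutation p was adjusted by the Benjamini-Hochberg method over 75 tests (15 lists in 5 comparisons). Genes are not independent replicates, so this p describes these region sets. The groups, the comparisons and their tests, the gene lists, the rule for named genes and all alternatives but those listed as added were chosen before the data were examined. The comparisons by chromosome and the overlaps between genotype-specific regions of different antibodies were not among them and were added with the data at hand. Tests of explanations and further observations that were chosen after the result was seen are named where they are given.

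The text names, for each comparison and direction, the 5 regions with the highest rank, ranked by the lowest within-list percentile of the score over the libraries that hold them, each gene once and only regions with a gene within 50 kb. For FOXA1, control-only regions were ranked by the percentile of peak width and treatment-specific regions by the scores of the mutant libraries, since the control lists hold no score. Of each list, up to 4 genes per direction qualified, those with most such regions first. The text gives a selection of these genes and does not always keep that order. The 10 genes counted per library whatever the result were Foxa1, Ar, Spop, Nkx3-1, Fkbp5, Tmprss2, Krt8, Krt5, Trp63 and Myc.

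The alternatives were peaks at −log10 q of at least 5, equal lists cut to the best-scored peaks at the length of the shortest list, windows of 200 bp around the summit, at least 50% of a region or peak covered, absence that allows 1 library, inclusion of other sequences, each library left out in turn, covered bases, a 5 kb window at gene ends, gene reach of 10 or 100 kb, and a replicate block. The following were added after seeing the data: FOXA1 lists cut to their widest peaks, random lists matched on chromosome, FOXA1 gene lists within each genotype, and genotype counts within each treatment. For FOXA1 the score and q alternatives could not be run, and 200 bp windows used midpoints in all 8 libraries.

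The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated data the overlap counts matched a base-by-base count in 200 of 200 intervals, 200 of 200 planted regions in 8 libraries were recovered, and 1 of 35 splits reached the planted count. Of 1000 gene lists with no change, 54 had a p under 0.05, and the 1 list with a planted excess was found.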

Results

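ChIP-seq peak lists of mouse prostate organoids were compared between control and SPOP-mutant cultures. SPOP is the substrate adaptor of a ubiquitin ligase, and it is mutated in part of human prostate cancers. The androgen receptor (AR) and the pioneer factor FOXA1 were profiled with H3K4me2, a histone mark of promoters and enhancers. Organoids were treated for 24 h with 10 nM dihydrotestosterone (DHT) or with ethanol (EtOH) in medium without mEGF. There were 20 libraries with peak lists, in 10 groups with n = 2 each. FOXA1 and H3K4me2 were measured in both genotypes with DHT and with EtOH, and AR in both genotypes with DHT. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

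The lists held 55447 to 66196 peaks for AR, 59258 to 105371 for FOXA1 and 95504 to 137314 for H3K4me2. Peaks covered a mean of 23.7 Mb in control and 22.9 Mb in mutant AR lists. Read depth was unknown, since the lists hold no read counts, and all intervals below cover counting error only. Between 63.5% and 85.4% of the peaks of a list overlapped a peak of the other replicate. In the AR lists the median −log10 q was 2.73 for control replicate 2 and 4.74 to 5.37 for the other 3 libraries. For H3K4me2 it was 3.83 to 4.01 in 3 mutant libraries, 5.81 in mutant DHT replicate 1 and 5.92 to 7.62 in the controls.

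**Figure D1:**
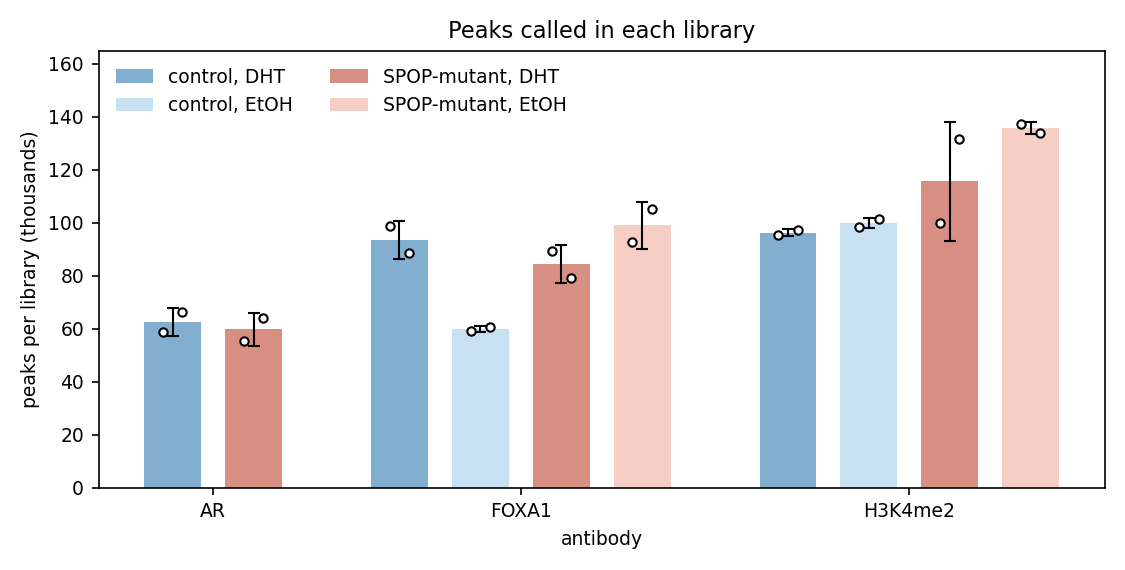
Peaks per library for each antibody, genotype and treatment; points are libraries, bars group means and error bars the SD (n = 2). The control EtOH FOXA1 lists (59258 and 60858 peaks) lie below the other 6 FOXA1 lists, and 3 of the 4 mutant H3K4me2 lists lie above the rest.

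The comparison of AR between genotypes asks where AR lies in mutant organoids and not in controls, and the reverse. The strongest mutant-only AR region lay 15.3 kb outside Prl (chromosome 13, 27042006–27042553, build mm10), which encodes prolactin. Next came regions inside Mecom (chromosome 3, 30254373–30254986), a zinc finger transcription factor gene, and inside Ctnnd2 (chromosome 15, 30338543–30339520), the gene of δ-catenin. Regions inside Tmtc3 and 3.79 kb from Stk33 completed the first 5. The strongest control-only AR region lay 6.90 kb from Actr3b (chromosome 5, 25752744–25753331), an actin-related gene, followed by a region inside the nucleoside transporter gene Slc28a3 (chromosome 13, 58600991–58601652). Regions inside Clstn2, 24.2 kb from Shisa6 and 40.3 kb from Mylip came next. In all, 6495 of 110199 AR regions were held by both mutant and neither control library, 5637 by both control and neither mutant library, and 28591 by all 4. Mutant-only regions were thus 53.5% of the genotype-specific ones (95% Wilson interval 52.6 to 54.4), but the balance depended on the libraries. With 1 library left out, mutant-only regions ranged from 8458 to 21054 and control-only regions from 7272 to 26001, since the side that lost a library then needs only 1. The other 2 splits of the 4 libraries gave at most 2020 regions on one side. With 2 libraries against 2 the smallest two-sided p is 0.333, so no call was possible. With peaks at −log10 q of 5 or more the counts were 4356 mutant-only and 2225 control-only (66.2% mutant-only), and control replicate 2 had the fewest such peaks (21757, against 26719 to 31296).

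Mutant-only AR regions lay beside 8 of 17 luminal progenitor genes and control-only regions beside 2. Runx1, a transcription factor gene, had 5 mutant-only regions, the hyaluronan receptor gene Cd44 had 4, and the keratin gene Krt7 and Plac8 had 3 each. Cd44 also had 2 control-only regions, and the pluripotency factor gene Sox2 had 1 of each kind. Runx1, Krt7 and Cd44 lie on chromosomes 16, 15 and 2, where mutant-only regions were 58.8%, 68.6% and 71.3% of the genotype-specific AR regions, and Plac8 lies on chromosome 5, where they were 42.8%. The list shifted by 10.8% of its 167 regions towards the mutant, where matched random lists gave 0.589% (permutation p 0.00442, adjusted p 0.166 over 75 tests). Matched on chromosome as well, the permutation p was 0.0256. Androgen targets had mutant-only regions at 12 and control-only regions at 10 of 27 genes. Among them, the kinase gene Sgk1 had 5 mutant-only regions and Ar 2, each with 1 control-only region, while the elongation factor gene Ell2 and the metalloreductase gene Steap4 had 3 control-only regions each. The transporter gene Abcc4 had 2 of each kind. Basal genes were marked in both directions (11 and 9 of 20). Bcl2 had 6 and the laminin receptor gene Itga6 had 3 mutant-only regions, whereas the basal master regulator Trp63 had 5, the growth factor gene Nrg1 4 and the hemidesmosome gene Col17a1 3 control-only regions. Trp63 and Nrg1 also had 1 and 2 mutant-only regions.

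Of the other AR lists, luminal markers had mutant-only regions at 10 and control-only regions at 5 of 19 genes. Cd24a and Ehf had 2 mutant-only regions each, and the homeobox gene Hoxb13 had 2 and Foxa1 had 1 control-only and 1 mutant-only region. Neuroendocrine genes had mutant-only regions at 2 (the granin gene Scg2 with 4, Neurod1 with 1) and control-only regions at 3 of 9, Mycn with 2. Wnt pathway genes were marked at 10 and 7 of 23, with 4 mutant-only regions at Wnt7b and 5 control-only regions at Znrf3, which encodes a Wnt receptor ligase and had 1 mutant-only region too. For the PI3K and mTOR pathway the numbers were 10 and 14 of 24. The phosphatase gene Phlpp1 had 3 mutant-only and 1 control-only region, the insulin receptor substrate gene Irs2 had 4 control-only regions, and Rptor had 2 of each kind. AP-1 and stress genes had 7 and 11 of 20, with Atf3 at 2 mutant-only and Fosl2, Klf4 and Tnfaip3 at 2 control-only regions each, beside 1 control-only region at Atf3 and 1 mutant-only region at Tnfaip3. SPOP substrates and BET proteins had 7 and 8 of 18, where Myc had 2 mutant-only and the Hedgehog effector Gli3 had 3 control-only regions. Steroid and lipid genes had 7 and 10 of 21, with Srd5a2 and Fads1 at 2 mutant-only and Srebf2 at 2 control-only regions. Cell cycle genes had 4 and 3 of 15, and Cdk6 had 2 mutant-only and 4 control-only regions. Stromal genes had 0 and 2 of 14 (Zeb1 and Twist1 in controls), and endothelial and immune genes 1 and 1 of 11. Housekeeping genes had 5 and 2 of 18, and other lineages 1 and 2 of 11.

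Control-only AR regions lay within 1 kb of a gene end in 15.4% of cases (14.4 to 16.3) and mutant-only regions in 5.31% (4.79 to 5.88), against 6.44% of the regions held by all 4 libraries. With peaks at −log10 q of 5 or more the control-only and mutant-only values were 6.07% and 3.37%. With 1 library left out they ranged from 12.9% to 15.6% and from 5.92% to 8.09%. Of all peaks per library, the share was 10.3% ± 0.0517 (SD, n = 2) in controls and 7.91% ± 0.750 (n = 2) in mutants.

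The FOXA1 comparison between genotypes asks the same of the pioneer factor, over 4 libraries against 4. The mutant-only regions of highest rank lay 4.65 kb from Entpd6 (chromosome 2, 150775681–150776970) and inside Sbf2 (chromosome 7, 110547407–110548658), where AR held the region in 2 libraries and H3K4me2 in 4. A region 4.46 kb from Gipc2 and regions inside the eyes absent gene Eya2 and inside Frmpd4 followed. The control-only regions of highest rank by width lay inside Cachd1 (chromosome 4, 100863548–100864812), the protocadherin gene Pcdh19 (chromosome X, 133655237–133656390), Plxdc2 and Tns3. The fifth lay 31.9 kb from Lrat, which encodes a retinol esterifying enzyme. FOXA1 regions held by every mutant and no control library numbered 4504 of 177773, and those held by every control and no mutant library 1201, so that 78.9% (77.9 to 79.99) were mutant-only. No other of the 35 splits of the 8 libraries gave as many regions on one side, and the next was the split by DHT, with 3344.

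The balance depended on treatment and on the length of the lists. With EtOH, 26033 regions were mutant-only and 2517 control-only (91.2% mutant-only), whereas with DHT 10674 were mutant-only and 12708 control-only (45.7%). With each list cut to its widest peaks at the length of the shortest list, 2549 were mutant-only and 1877 control-only (57.6%). The control lists carry positions without scores, so the layout of the files coincided with genotype. With EtOH the mutant lists held 99124 ± 8835 peaks and the control lists 60058 ± 1131, and with DHT the order was the reverse, with 84358 ± 7193 and 93678 ± 7213 (SD, n = 2 each). Over both treatments the log2 difference in peak number was 0.28 and did not pass (exact permutation p 0.257, 4 against 4). Of all FOXA1 peaks, 50.5% in mutant and 48.5% in control lists lay inside a gene span (exact permutation p 0.0286, 4 against 4). Within 1 kb of a gene end lay 8.79% and 7.60% (exact permutation p 0.257, 4 against 4).

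Mutant-only FOXA1 regions lay beside 9 of 28 androgen targets and control-only regions beside 4 (shift 1.91%, matched random lists 2.23%). Matched random lists leaned to the mutant as well, since 78.9% of the genotype-specific FOXA1 regions were mutant-only. The acyltransferase gene Mboat2 had 4 mutant-only regions, Ar had 2 and the protease gene Tmprss2 had 2, while Ell2 had 1 control-only region and Abcc4, Fkbp5 and Sgk1 had 1 of each kind. Luminal genes had mutant-only regions at 5 and control-only regions at 0 of 20 (shift 2.99%, matched random lists 2.20%). There were 2 each at Cd24a, Foxa1 itself and the tetraspanin gene Tspan8. Luminal progenitor genes had 6 and 1 of 18, with 4 mutant-only regions at Basp1, 2 at Runx1, and 1 each at Krt7 and the surface antigen gene Ly6a. The control-only one was at Cd44. Basal genes had 6 and 3 of 20 (shift 1.32%, matched random lists 2.25%). Bcl2 had 4 and Dst 3 mutant-only regions, and the growth factor receptor gene Egfr had 2 control-only regions, with 1 each at Lamc2 and Nrg1. Egfr and Nrg1 also had 1 mutant-only region each. Neuroendocrine genes had 2 and 0 of 14, with 5 mutant-only regions at Scg2 and 1 at Syp (permutation p 0.0105, adjusted p 0.196). Scg2 and Bcl2 lie on chromosome 1, where 87.0% of the genotype-specific FOXA1 regions were mutant-only.

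PI3K and mTOR genes had mutant-only FOXA1 regions at 7 and control-only regions at 2 of 24 (shift 2.23%, matched random lists 2.25%). The insulin receptor substrate gene Irs1 had 4 and Phlpp1 had 3 of the former, and Pik3r1 had 1 of the latter. Steroid and lipid genes had 7 and 0 of 21, with 2 at the desaturase gene Fads2 (shift 2.90%, matched random lists 2.10%). SPOP substrates and BET proteins had 6 and 2 of 20, with Myc at 2 mutant-only regions and the Hedgehog effectors Gli2 and Gli3 at 1 control-only region each, beside 1 mutant-only region at Gli3. Wnt genes had 4 and 2 of 23 (shift 1.03%, matched random lists 2.21%). Lgr4 and Tcf7l2 had 2 mutant-only regions each, and Fzd7 and Lgr6 had 1 control-only region each. AP-1 and stress genes had 2 (Atf3 and Fos) and 1 (Klf4) of 20. Stromal genes had 1 (Des) and 1 (Zeb1, with 2 regions) of 14, and endothelial and immune genes 2 (Itgam and Ptprc) and 0 of 12. Cell cycle genes had 1 (Cdk1) and 0 of 17, housekeeping genes 4 and 0 of 18, and other lineages 2 (Hnf4a and Ttr) and 0 of 13.

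**Figure D2:**
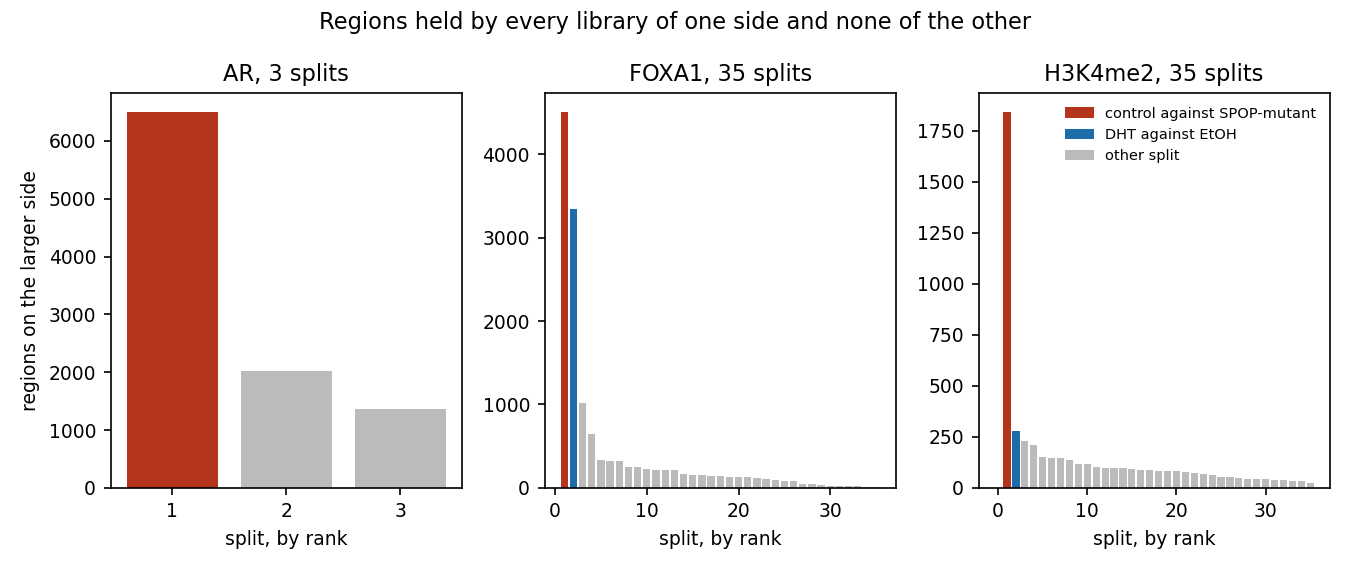
Regions held by every library of one side and none of the other (larger side, bars) for each of the 3 splits of the AR libraries and the 35 splits of the FOXA1 and of the H3K4me2 libraries, by rank. The genotype split is the highest for each antibody (6495, 4504 and 1841 regions), and the DHT split is the next for FOXA1 and H3K4me2 (3344 and 281).

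The H3K4me2 comparison asks which promoters and enhancers carried the mark in only 1 genotype. The highest-ranked mutant-only regions lay 2.99 kb from the ribosomal protein gene Rpl12 (chromosome 2, 32965885–32968176) and inside Lrpprc. A region of 7935 bp inside Plac8, a luminal progenitor gene, followed (chromosome 5, 100565696–100573630). Regions inside the DNA repair gene Mgmt and the glutathione transferase gene Gsta3 came next. The highest-ranked control-only regions lay inside the axon guidance gene Rgma (chromosome 7, 73397746–73400025), the sphingosine receptor gene S1pr1 (chromosome 3, 115712975–115715927) and Ptn, 0.049 kb from the homeobox gene Isl1, and inside Rnf207. Regions held by every mutant and no control library numbered 1833 of 150847, and those held by every control and no mutant library 1841, or 49.9% mutant-only (48.3 to 51.5). No other of the 35 splits gave more than 281.

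Which genotype had more H3K4me2 regions of its own depended on the peaks used. With peaks at −log10 q of 5 or more, 444 were mutant-only and 2200 control-only (16.8% mutant-only). With equal lists by score the counts were 806 and 2739 (22.7%), and with at least 50% of each region covered 1549 and 2747 (36.1%). With 1 library left out, mutant DHT replicate 1, the mutant-only count was 3142. Peak number was higher by 0.35 on the log2 scale in mutants (exact permutation p 0.0571, 4 against 4), and without mutant DHT replicate 1 by 0.45 (exact permutation p 0.0286, 3 against 4). Counting only peaks at −log10 q of 5 or more, the difference was −0.062 (exact permutation p 0.171, 4 against 4). Of all H3K4me2 peaks, 11.7% in mutant and 13.7% in control lists lay within 1 kb of a gene end, a difference of −2.04 percentage points (exact permutation p 0.0286, 4 against 4). With equal lists by score the difference was −0.126 points (exact permutation p 0.714, 4 against 4). Inside a gene span lay 57.2% in mutant and 56.1% in control lists (exact permutation p 0.0571, 4 against 4). Of the mutant-only regions 4.20% (3.37 to 5.22) lay within 1 kb of a gene end, and of the control-only regions 16.0% (14.4 to 17.7). Inside a gene span lay 58.4% of the mutant-only and 51.2% of the control-only regions.

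Luminal progenitor genes had mutant-only H3K4me2 regions at 3 (Krt7 with 3, Krt4 and Plac8 with 1 each) and control-only regions at 0 of 18. Steroid and lipid genes had 5 and 0 of 21, with 1 mutant-only region each at Acaca, Elovl5, Insig1 and Sqle, all enzymes or regulators of lipid synthesis. Luminal genes had 1 (Cldn3) and 5 of 20, with control-only regions at the E-cadherin gene Cdh1, Gata3 and Krt8. Stromal genes had 0 and 3 of 12, with 2 control-only regions at Twist1 and 1 each at Dcn and Myh11 (permutation p 0.0175, adjusted p 0.219). Androgen targets had 3 and 3 of 25. Acsl3 had 3, Mboat2 had 2 and the chaperone gene Fkbp5 had 1 mutant-only region, and Abcc4 had 4, Nkx3-1 had 1 and Steap4 had 1 control-only region. Basal genes had 4 and 2 of 20, with 3 mutant-only regions at Bcl2 and 1 at Sox9, 2 control-only regions at Dst and 1 at Trp63. Neuroendocrine genes had 2 (Scg2 and Syp, 2 regions each) and 1 (Ascl1) of 14 (permutation p 0.0322, adjusted p 0.302). With 1 library left out, the excess of this list over matched random lists ranged from 1.03 to 8.25 points. Wnt genes had 2 and 5 of 24, with 2 mutant-only regions at Lgr4, 1 at Lgr5 and 2 control-only regions at Lgr6. AP-1 and stress genes had 1 and 4 of 20, with control-only regions at Gadd45a, Klf4 and Klf6. PI3K and mTOR genes had 4 and 2 of 24 (Rptor with 2 mutant-only, Akt3 with 2 control-only regions). SPOP substrates and BET proteins had 3 (Gli3, Myc and Ncoa3) and 3 (Brd4, Gli3 and Macroh2a1) of 20. Endothelial and immune genes had 1 (Ptprc) and 1 (Tek) of 12, cell cycle genes 0 and 2 (Cdk6 and Cdkn2a) of 20, housekeeping genes 2 and 0 of 20, and other lineages 0 and 1 (Olig2) of 15.

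**Figure D3:**
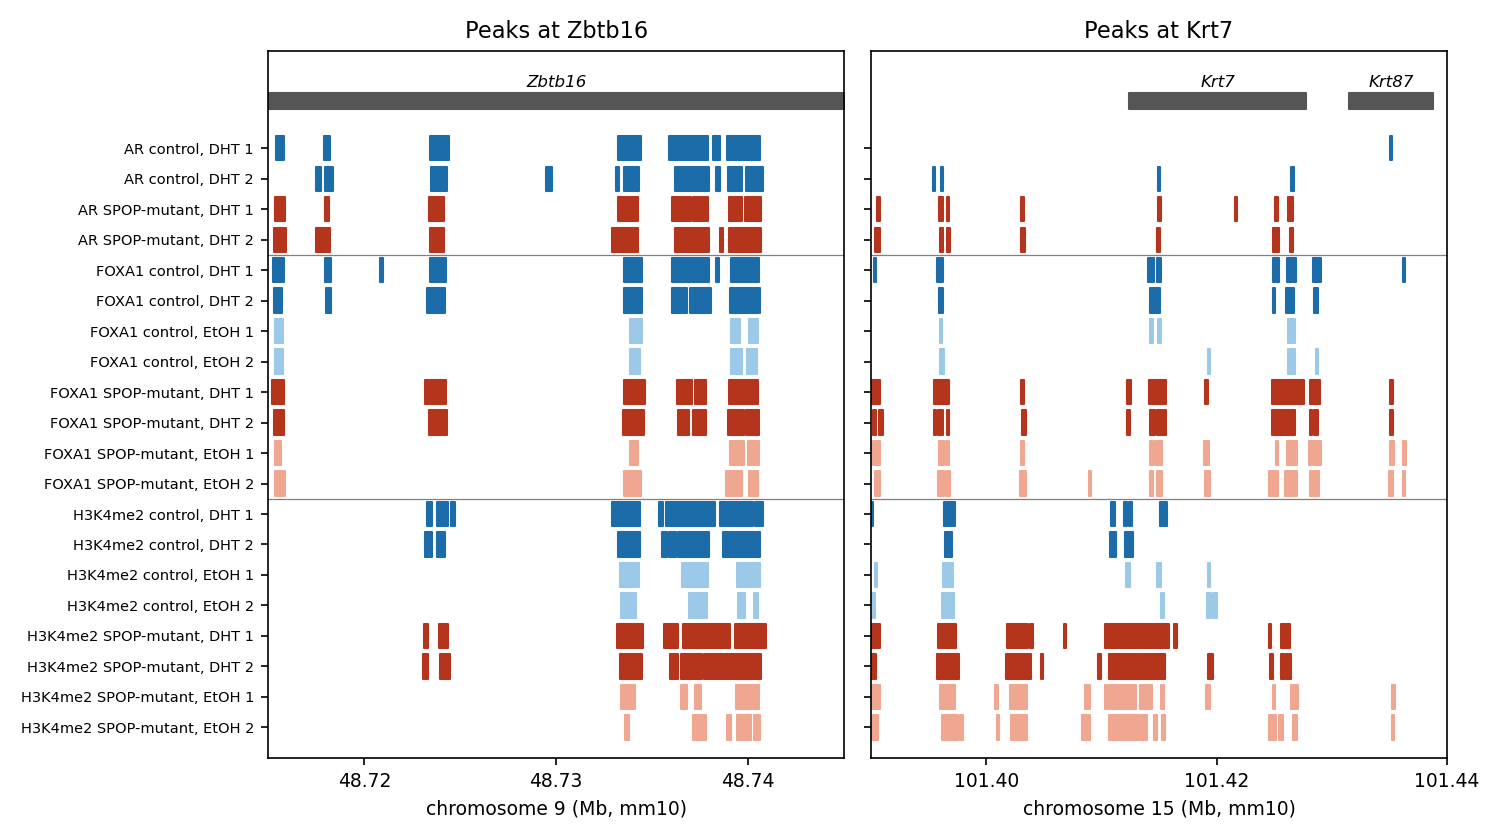
Peaks of each of the 20 libraries (bars) at Zbtb16 and Krt7, with position in Mb (build mm10) on the horizontal axis, gene spans in grey, controls in blue, mutants in red and EtOH libraries in lighter shades. In the region inside Zbtb16 that starts at 48723156, FOXA1 and H3K4me2 peaks appear in the DHT libraries of both genotypes, and to the left of Krt7 H3K4me2 peaks appear that the 4 mutant libraries hold and no control library does.

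Most genotype-specific regions of 1 antibody overlapped none of another, and those that did mostly agreed in direction. Of the 4504 mutant-only FOXA1 regions, 161 overlapped a mutant-only and 1 a control-only H3K4me2 region, and 313 overlapped a mutant-only and 22 a control-only AR region. Of the 1201 control-only FOXA1 regions, 0 overlapped a mutant-only and 122 a control-only H3K4me2 region, and 3 and 288 overlapped mutant-only and control-only AR regions. Of the 6495 mutant-only AR regions, 285 overlapped a mutant-only and 1 a control-only H3K4me2 region. Of the 5637 control-only AR regions, 5 overlapped a mutant-only and 235 a control-only H3K4me2 region.

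Chromosomes differed in the balance. On chromosome 2, mutant-only regions were 71.3% of the genotype-specific AR regions, 90.6% of the FOXA1 regions and 67.7% of the H3K4me2 regions, and on chromosome 15, which carries Myc and Krt7, 68.6%, 91.8% and 71.6%. On chromosome 14 the shares were 34.2%, 55.8% and 24.5%, and on chromosome 10 they were 46.9%, 65.7% and 27.5%. Chromosome X had 72.2% for AR, 80.1% for FOXA1 and 46.8% for H3K4me2. Over the 20 chromosomes the log2 ratio of mutant-only to control-only regions correlated between FOXA1 and H3K4me2 (Spearman rho 0.919, permutation p 1e-05, the smallest the permutations can give, adjusted p 7e-05; Pearson r 0.935, permutation p 1e-05). Between AR and H3K4me2, rho was 0.785 (permutation p 9e-05, adjusted p 0.00021) and r 0.784 (permutation p 8e-05). Between AR and FOXA1, rho was 0.770 (permutation p 0.00015, adjusted p 0.000262) and r 0.804 (permutation p 3e-05). Without the 2 chromosomes farthest from the median, r was 0.904, 0.856 and 0.840. These 3 relations were among 7 computed in the family, and chromosomes are not independent replicates. Per library, 8.51% ± 0.172 of mutant and 6.93% ± 0.1504 of control FOXA1 peaks lay on chromosome 2 (n = 4 each, exact permutation p 0.0286, adjusted p 0.0408). In all, 14 of 20 chromosomes passed for FOXA1 at that adjusted p. The share was higher in mutants on chromosomes 1, 2, 3, 7, 9, 15 and X, and lower on chromosomes 5, 6, 8, 10, 13, 14 and 18. For H3K4me2 the shares on chromosome 2 were 7.67% and 7.32% (n = 4 each, exact permutation p 0.0286, adjusted p 0.0571). All 4 mutant lay apart from all 4 control H3K4me2 libraries on 10 chromosomes, with the share higher in mutants on 1, 2, 3, 7, 15 and 16 and lower on 8, 10, 13 and 14. Each had the smallest p that 4 against 4 can give, but none passed after adjustment (adjusted p 0.0571), since fewer chromosomes reached it than for FOXA1. Only the FOXA1 files differed in layout between genotypes.

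**Figure D4:**
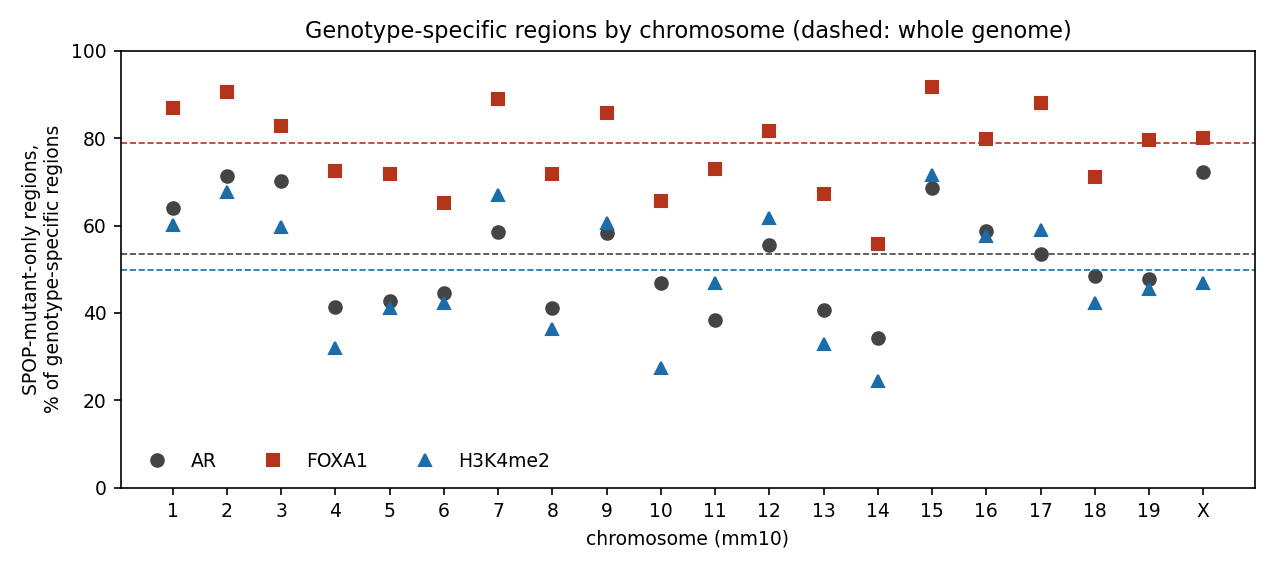
Mutant-only regions as a percentage of genotype-specific regions on each chromosome for AR, FOXA1 and H3K4me2 (points), with dashed lines for the whole genome. Chromosomes 2 and 15 lie above and chromosome 14 lies farthest below the line of each antibody.

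The comparison of FOXA1 between DHT and EtOH asks where androgen places the pioneer factor. The highest-ranked DHT-only FOXA1 region lay inside Zbtb16 (chromosome 9, 48723156–48724303), a zinc finger gene induced by androgen and glucocorticoid. AR held that region in 4 of 4 libraries, H3K4me2 in 4 of 8. The next regions lay inside the pyrimidine catabolism gene Dpyd (chromosome 3, 119288039–119289215), 27.8 kb from Pcmtd1, 14.6 kb from Tigd2 and inside the desaturase gene Scd3. The highest-ranked EtOH-only regions lay inside Macrod2 (chromosome 2, 141173634–141174134), Tafa1 and Ggnbp2, 8.57 kb from Lratd1 and 10.5 kb from Atp5g2. FOXA1 regions held by all 4 DHT and no EtOH library numbered 3344, and the reverse 295, or 91.9% DHT-only (91.0 to 92.7). Of the 35 splits, 2 gave as many regions on one side, this one and the split by genotype, so the share of 0.0571 did not pass 0.05. The highest count of a split outside these comparisons was 1021, and with equal lists by width the counts were 2218 and 418 (84.1% DHT-only).

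In control organoids 17942 FOXA1 regions were DHT-only and 1597 EtOH-only (91.8% DHT-only). In mutant organoids 8915 were DHT-only and 14302 EtOH-only (38.4%). With equal lists by width, controls had 7671 and 4627 (62.4%) and mutants 7913 and 6436 (55.1%), so the direction in mutants turned. Without mutant DHT replicate 2, 53.1% of the regions in mutants were DHT-only, but DHT-only regions then need 1 library and rise by construction. AR lay in 30.5% of the DHT-only and 9.33% of the EtOH-only FOXA1 regions of controls, and in 32.9% and 10.8% of those of mutants. Of the 3344 regions DHT-only in both genotypes, 59.4% (57.7 to 61.0) were held by AR in mutants and 37.6% (35.9 to 39.2) in controls. This difference rests on 2 AR libraries per genotype, and the intervals cover counting error only. AR control replicate 2 had the lowest median −log10 q of the AR lists (2.73), and its part in the difference was not tested.

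Androgen targets had DHT-only FOXA1 regions at 10 and EtOH-only regions at 0 of 28 genes (permutation p 0.00969, adjusted p 0.196). Fkbp5 had 4, the leucine zipper gene Tsc22d3 and Zbtb16 had 3 each, and Abcc4 had 2. Basal genes had 7 and 0 of 20, with 4 at Nrg1, 3 at Bcl2, 3 at Trp63 and 1 at Col17a1. Luminal genes had 6 and 1 of 20, among them Ar, Ehf and Elf3 with 1 DHT-only region each, and Cdh1 with 1 of each kind. PI3K and mTOR genes had 8 and 0 of 24, with 2 each at Irs2 and Pik3r1 (shift 1.86%, matched random lists 1.73%). Matched random lists leaned to DHT too, since 91.9% of the treatment-specific FOXA1 regions were DHT-only. Lists given here without a permutation p had one above 0.05. AP-1 and stress genes had 6 and 0 of 20, with 2 each at the phosphatase gene Dusp1 and at Tnfaip3. Wnt genes had 6 and 4 of 23, where the feedback inhibitor gene Axin2 had 2 DHT-only and 1 EtOH-only region, and Lgr6, Tcf7l2 and Wnt7a had 1 EtOH-only region each. Luminal progenitor genes had 4 and 0 of 18 (Cd44 with 3), SPOP substrates and BET proteins 3 and 0 of 20 (Dek and Gli3 with 1 each), and steroid and lipid genes 3 and 1 of 21 (Hmgcs1 DHT-only, Hmgcr EtOH-only). Stromal genes had 2 and 0 of 14 (Zeb1 with 2, Dcn with 1; permutation p 0.0465, adjusted p 0.388). Genes of other lineages had 5 and 0 of 13, Alb, Gata1, Hnf4a and Map2 among them (permutation p 0.00223, adjusted p 0.166). Cell cycle genes had 1 (Cdk6) and 0 of 17, housekeeping genes 2 and 0 of 18, and neither neuroendocrine nor endothelial and immune genes had any.

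The comparison of H3K4me2 between DHT and EtOH asks where androgen changes the mark, and it found few regions. The region of highest rank with DHT was again inside Zbtb16 (chromosome 9, 48723807–48724478), followed by regions 0.059 kb from Fnbp1l, 1.78 kb from 1700012B09Rik, inside Fras1 and 33.3 kb from Pja1. With EtOH they lay inside Gnaq (chromosome 19, 16310680–16311401), 5.57 kb from Rnf11, 9.24 kb from Ifrd1, 10.7 kb from the cholesterol synthesis gene Sc5d and inside Ints7. The lowest within-list percentile of the score was 41.5 for the first DHT-only and 51.5 for the first EtOH-only region. Even the first-ranked regions thus lay near or below the middle of a list that held them. There were 61 DHT-only and 281 EtOH-only H3K4me2 regions (17.8% DHT-only, 14.1 to 22.2). Of the 35 splits, 2 gave as many, this one and the split by genotype, which is not under 0.05. With equal lists by score the counts were 104 and 147 (41.4%) and 4 splits gave as many, and with 200 bp windows they were 228 and 496 (31.5%) and 5 splits gave as many. AR held 62.3% of the DHT-only H3K4me2 regions in controls and 59.0% in mutants, and 20.3% and 19.2% of the EtOH-only ones. In controls 1446 regions were DHT-only and 3265 EtOH-only, and in mutants 1799 and 5882. With a DHT library left out, a DHT-only region needs 1 library and an EtOH-only region still 2, so the former rise by construction. Without control DHT replicate 2 the counts were 7300 and 5308, and without mutant DHT replicate 1 they were 15395 and 9221.

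Among the fixed lists, DHT-only H3K4me2 regions lay beside the androgen target Zbtb16 (2 regions) and beside Brd4 and Gli3 of the SPOP substrates and BET proteins (permutation p 0.0167, adjusted p 0.219). EtOH-only regions lay beside Dkk1, Sfrp1 and Tcf7l2 of the Wnt pathway (permutation p 0.032, adjusted p 0.302), Inpp4b and Sgk1 of the PI3K and mTOR pathway, Gata3 of the luminal, Ltf of the luminal progenitor, Klf6 of the AP-1 and stress and Ccnd1 of the cell cycle genes. Sgk1 is also an androgen target. The excess of the Wnt list over matched random lists ranged from −0.843 to 0.0637 points with 1 library left out, so its direction was not kept throughout. The basal, neuroendocrine, stromal, endothelial and immune, steroid and lipid, housekeeping and other lineage lists had none in either direction.

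By the permutation test of gene lists with Benjamini-Hochberg adjustment, 0 of the 75 list tests passed 0.05. There were 9 with an unadjusted p under 0.05, and 9 when random lists were matched on chromosome. The lowest adjusted p was 0.166. With equal lists by score for AR and H3K4me2, 3 recomputed lists had an adjusted p of 0.0456. These were luminal progenitor markers for AR (25 mutant-only and 4 control-only regions), stromal markers for H3K4me2 by genotype (0 and 6), and androgen targets for H3K4me2 by DHT (4 and 1). The FOXA1 lists hold no common score and kept their p from all peaks, among them other lineages by DHT (permutation p 0.00223), which lowers the adjusted p of the other 3. Without AR control DHT replicate 1, 1 passed, the luminal progenitor markers for AR (32 and 18 regions, adjusted p 0.0262).

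AR and FOXA1 were compared directly to ask how far AR lay at FOXA1 sites in each genotype. With DHT, 66.7% ± 6.42 (SD, n = 2) of control AR peaks and 65.1% ± 2.38 (n = 2) of mutant AR peaks overlapped FOXA1 of their own genotype, where peaks shifted by 100000 bp gave 5.86% and 5.70%. For H3K4me2 with DHT the shares were 67.8% ± 5.10 and 65.7% ± 1.12 (n = 2 each), against 11.1% and 11.2% after the shift. The difference between genotypes was smaller than both SDs for FOXA1, and for H3K4me2 smaller than the SD in controls but not in mutants. Against FOXA1 of the other genotype with DHT, the shares were 54.2% ± 4.27 for control and 68.9% ± 2.52 for mutant AR peaks (n = 2 each). Mutant AR peaks thus overlapped mutant FOXA1 no more often than control FOXA1. FOXA1 lay in both control DHT libraries at 55.4% (54.2 to 56.6) of the mutant-only AR regions and in both mutant DHT libraries at 73.1% (72.0 to 74.1). At the control-only AR regions the shares were 59.6% (58.3 to 60.9) and 25.3% (24.2 to 26.4). These shares depended on requiring both AR libraries. Without AR mutant replicate 1 the mutant-only shares were 34.3% and 43.2%, and without replicate 2 they were 35.3% and 44.3%. Without AR control replicate 1 the control-only shares were 26.4% and 15.3%, and without replicate 2 they were 41.05% and 20.6%. In each case FOXA1 was more frequent in the genotype that held AR. H3K4me2 with DHT lay at 31.8% of the mutant-only AR regions in controls and at 44.7% in mutants, and at 70.2% and 57.9% of the control-only AR regions. At AR regions held by all 4 libraries FOXA1 lay at 91.2% and 81.1%, and H3K4me2 at 80.9% and 82.4%.

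**Figure D5:**
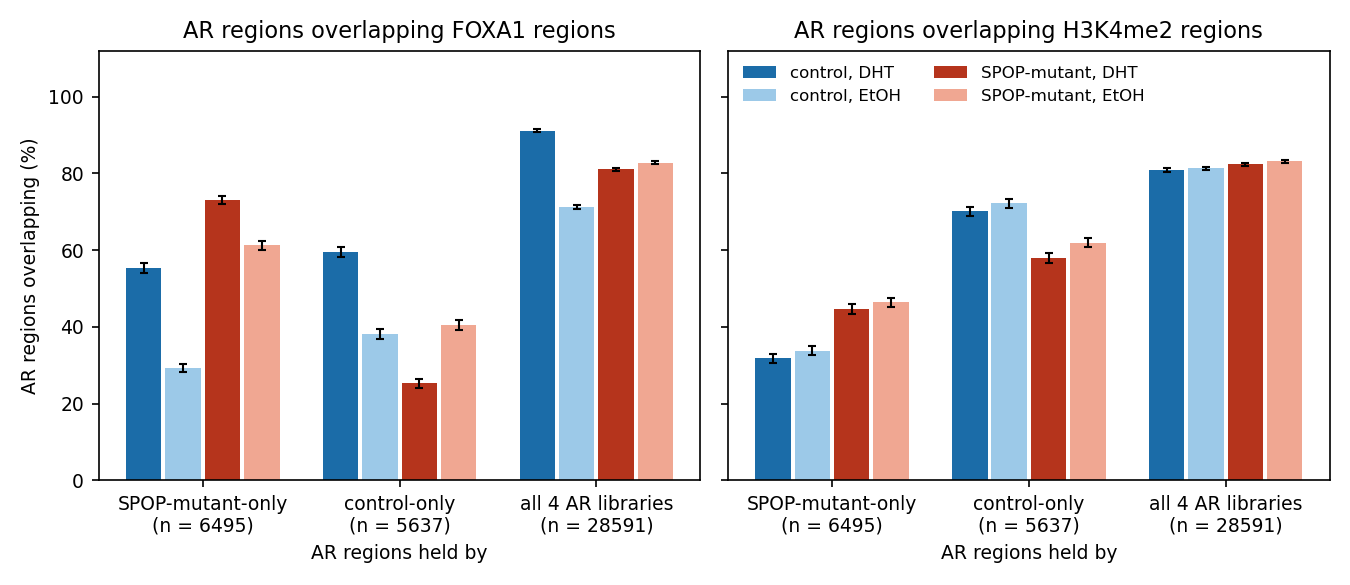
Share of AR regions (percent, bars, with 95% Wilson intervals) that overlapped FOXA1 or H3K4me2 in both libraries of each genotype and treatment, for mutant-only, control-only and shared AR regions. FOXA1 with DHT in mutants lay at 73.1% of mutant-only and 25.3% of control-only AR regions.

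For the 10 genes chosen in advance, regions within 50 kb were counted per library and are given as replicates 1 and 2. Trp63 had 41 and 43 AR regions in controls and 26 and 32 in mutants, and with DHT 45 and 37 FOXA1 regions in controls and 27 and 23 in mutants. Myc had 11 and 10 AR regions in controls and 15 and 17 in mutants. Around Fkbp5, FOXA1 regions in controls numbered 36 and 29 with DHT and 8 and 10 with EtOH, and in mutants 38 and 30 with DHT and 22 and 25 with EtOH. At Nkx3-1, a luminal homeobox gene, controls had 4 and 3 FOXA1 regions with DHT and 0 and 0 with EtOH, and mutants 5 and 3 with DHT and 5 and 5 with EtOH. Spop had 23 and 21 FOXA1 regions in controls with DHT and 9 and 10 with EtOH, against 15 and 14, then 16 and 21, in mutants. Foxa1 had 8 H3K4me2 regions in each of the 4 control libraries and 11 to 14 in the mutants. Tmprss2 had 31 and 33 AR regions in both genotypes. Ar had 13 and 13 AR regions in controls and 14 and 16 in mutants, Krt8 14 and 14 against 17 and 18, and Krt5 24 and 20 against 19 and 20. These counts were not tested singly and were not scaled to the length of the lists. The control EtOH FOXA1 lists were the shortest (59258 and 60858 peaks). Mean FOXA1 counts were lowest in that group also at Tmprss2 (25), Krt8 (14.5), Krt5 (12) and Myc (9), with n = 2 each.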

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

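Of the tests in this part, those on the layout of the FOXA1 files, on weak FOXA1 sites, on FOXA1 lists of equal length (cut to the widest peaks) and on the length of the mutant EtOH lists were chosen only after the result was seen. The splits of the libraries were planned, but the bound for reading them as chance was set after their counts were seen, and the others were set beforehand.

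FOXA1 peak number lay higher with DHT in the control lists and lower in the mutant lists, but the difference between genotypes did not pass. It was 0.64 higher with DHT on the log2 scale in controls (93678 ± 7213 peaks against 60058 ± 1131, SD, n = 2 each), and the difference was −0.23 in mutants (84358 ± 7193 against 99124 ± 8835, n = 2 each), a difference of 0.87 (exact permutation p 0.0571). Both control DHT lists were longer than both control EtOH lists, and both mutant DHT lists shorter than both mutant EtOH lists. In controls, DHT-only regions were still 1.66 times as many as EtOH-only ones (1.60 to 1.72) in the lists of equal length. This does not decide whether short EtOH lists are the whole cause. The cut keeps the shortest EtOH list whole but only the widest peaks of the DHT lists, and the interval covers counting error only. AR lay in 27.2% (26.6 to 27.9) of control DHT-only regions at matched width and in 9.33% (7.999 to 10.9) of EtOH-only ones. AR was profiled only with DHT, so this does not decide whether the gained sites are weak sites anywhere in the genome. In mutants, longer EtOH lists may account for the excess of EtOH-only regions, since in lists of equal length these were 0.813 times the DHT-only ones. A real difference in androgen response between the genotypes stays open and was not separated from the yield of the libraries.

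Chromosomes with more mutant-only regions of 1 antibody had more of the others, as at Krt7 and Myc on chromosome 15 and Scg2 and Bcl2 on chromosome 1. For AR and H3K4me2, list length is argued against as the cause. With equal lists the SD over chromosomes stayed at 1.01 times its value for AR and 1.02 times for H3K4me2. FOXA1 was not tested in this way. The layout of the FOXA1 files is argued against by AR and H3K4me2, whose files share a layout and whose ratios correlated at rho 0.785. A difference in chromosome copy number between the control and mutant organoids cannot be told apart from a change in binding. The near and far parts of the chromosomes agreed for H3K4me2 (rho 0.617), AR (rho 0.744) and FOXA1 (rho 0.802), as copy number predicts. Between the DHT ratio of FOXA1, which compares like organoids, and the H3K4me2 genotype ratio, rho was 0.421 (permutation p 0.066) and r 0.350 (permutation p 0.13). Neither passed, and the bound set beforehand for rho was under 0.4, so this value does not decide.

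The balance of H3K4me2 mutant-only and control-only regions, near even with all peaks, turned to controls at −log10 q of 5 or more. Mutant DHT replicate 1 held 16.6% (15.2 to 18.0) of the 2637 regions of 4 controls that the other 3 mutants lacked, and the other 3 held 6.66%, 14.6% and 15.03% of the like regions. The bound set beforehand, under 20%, was wrong as a test of weaker enrichment in 3 of the 4 mutant libraries. It rests on 1 library, and the median −log10 q of that library (5.81) lies below every control (5.92 to 7.62). Weaker enrichment therefore cannot be told apart from a loss of strong H3K4me2 sites in mutants. Read counts in these regions, scaled on regions that all 8 libraries hold, would test it, and reads were not analysed here.

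By genotype, 1 of 35 splits, the real one, gave 4504 FOXA1 regions (highest other 3344) and 1 of 35 gave 1841 H3K4me2 regions (highest other 281). Even if replicates were separate cultures, this does not exclude chance, since splits that divide DHT and EtOH libraries unevenly can be low through treatment alone. The labels also do not say whether each genotype came from more than 1 line or mouse. If replicates were technical, splits that part them are low by construction, and the 3 splits that keep each group whole are too few for a share under 0.05. For DHT, chance cannot be excluded by the share of splits either. There 2 of 35 splits gave as many for FOXA1 (3344, highest other 4504) and for H3K4me2 (281, highest other 1841), and in both cases the larger split was the one by genotype. The highest count of a split outside the comparisons by genotype and DHT was 1021 for FOXA1 and 232 for H3K4me2.

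Outside chromosomes 1 to 19, X and Y the FOXA1 and H3K4me2 lists held 233 peaks, which entered only the alternative that included other sequences. There were 7 to 21 per list, and 0 in the AR lists. On the unplaced sequence JH584304, a peak ranked first by p in 5 of the 8 H3K4me2 lists, with a fold enrichment of 6.44 to 8.54 over the 8, and no explanation was tested.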

How the results depend on the processing

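Tests within each treatment and on FOXA1 lists cut to their widest peaks were chosen only after the result was seen; the cause was not tested for results that moved, except where construction shows it. Depth was unknown, so how far it limits a list is not known. At −log10 q of 5 or more, AR control-only regions fell to 2225, H3K4me2 mutant-only to 444, H3K4me2 DHT-only and EtOH-only to 31 and 123 (3 of 35 splits as large), and the genotype difference in H3K4me2 peak number was −0.062. Equal lists by score gave 806 H3K4me2 mutant-only regions, 104 DHT-only and 147 EtOH-only (4 of 35), a genotype difference near gene ends of −0.126 points, and 4 passing gene lists, of which 1 was a FOXA1 list that kept its value from all peaks. Windows of 200 bp gave 228 and 496 (5 of 35). With the widest FOXA1 peaks, 2549 were mutant-only, 1877 control-only and 2218 DHT-only, with 7671 and 4627 DHT-only and EtOH-only in controls and 6436 EtOH-only in mutants. With 50% coverage 2470 FOXA1 regions were EtOH-only in controls.

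Counts that require fewer libraries rise by construction. Where absence allowed 1 library, FOXA1 had 7844 mutant-only, 2161 control-only and 920 EtOH-only regions, and H3K4me2 had 3290, 3198, 245 DHT-only and 1029 EtOH-only. Within DHT, FOXA1 had 10674 mutant-only and 12708 control-only and H3K4me2 6142 and 5295, and within EtOH 26033 and 2517, and 8453 and 4709. With 1 library left out, AR mutant-only ranged from 8458 to 21054 and control-only from 7272 to 26001. FOXA1 EtOH-only ranged from 356 to 759, in controls DHT-only from 17977 to 40925 and EtOH-only from 1595 to 8892, and in mutants from 8917 to 19607 and from 14330 to 32354. H3K4me2 mutant-only ranged from 2093 to 3142 (the highest without mutant DHT replicate 1), DHT-only from 88 to 178 and EtOH-only from 433 to 691, with 5 to 8 of 35 splits as large.

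By library, the H3K4me2 genotype difference in peak number ranged from 0.30 to 0.45, and its interaction with DHT from −0.0089 to 0.39, both turning on mutant DHT replicate 1. The DHT difference in covered bases for H3K4me2 was −0.14 (exact permutation p 0.0286), where peak number gave −0.15 (exact permutation p 0.2). Near gene ends the H3K4me2 genotype difference was −0.997 points within 5 kb and −2.50 to −1.71 with 1 library left out (exact permutation p 0.0571 without any 1 control), and the DHT difference within 5 kb was 1.57. For FOXA1 by DHT it ranged from 0.514 to 1.62, the highest without mutant EtOH replicate 2 (exact permutation p 0.0286). AR peaks with FOXA1 in either library were 75.9% in controls and 74.6% in mutants, and 63.4% to 70.02% in mutants with 1 library left out. Passing gene lists ranged from 0 to 1. Of the main results, 292 recomputed under planned and 6 under added alternatives kept direction and side of the threshold, or stayed within 1.5 times. Under planned ones 58 moved, 2 turned direction, 6 no longer passed and 4 newly passed, and under added ones 14 moved. Of values for single lists, region classes and H3K4me2 counts within a genotype, 133 planned and 13 added did so, 61 moved and 3 passed where they had not. The 292 include region counts under the replicate block, which leaves a count unchanged, so these could not move.

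Replicate numbers did not pair the samples (correlations of deviations −0.0222 to 0.00765), and with the replicate block 1 of 18 splits gave as many FOXA1 genotype regions (4504) and 2 of 18 as many DHT-only ones (3344). The FOXA1 genotype difference in peak number was 0.28 (exact permutation p 0.333). It changed no call except where its smallest p, 0.0556, cannot pass. Motif alternatives, FOXA1 lists by q or score, and AR with FOXA1 at equal length were not run.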

Other observations

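The tests of gene lists within each genotype and the values on Y genes in this part were chosen only after the result was seen.

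In control organoids, DHT-only FOXA1 regions lay at most AP-1 and stress genes, as at most genes of several other lists. Of the 20 genes, 18 had such regions (51 in all), and 1 had an EtOH-only region. Among other lists, 16 of 20 basal, 19 of 24 PI3K and mTOR, 20 of 28 androgen target and 9 of 18 luminal progenitor genes had DHT-only regions. Klf4 and the phosphatase gene Dusp1 had 7 each, the NF-kB inhibitor gene Tnfaip3 had 6, and Jun and Fosl2 had 4 each. In mutants the same genes had DHT-only and EtOH-only regions at 1 and 3 (Klf4), 2 and 2 (Dusp1), 4 and 3 (Tnfaip3), 1 and 4 (Jun) and 1 and 1 (Fosl2), with 16 and 22 over the list. In controls the list shifted by 15.5% of its 322 regions, where matched random lists gave 9.24% (permutation p 0.00092, adjusted p 0.0276 over 30 tests and 0.0966 over 105). With random lists matched on chromosome as well, the call was lost (permutation p 0.00254, adjusted p 0.0762 over 30 tests). In mutants the permutation p was 0.621, and the difference between genotypes was not tested. With FOXA1 lists cut to their widest peaks, controls had 24 and 3 (permutation p 0.0152), and without control DHT replicate 2 they had 82 and 2 (permutation p 0.185). With any other control library left out the permutation p was 1e-05 to 0.00212, where 1e-05 is the smallest the permutations can give. Androgen targets in controls had 64 DHT-only and 3 EtOH-only regions, a shift of 11.7% where matched random lists gave 9.18% (permutation p 0.116, adjusted p 0.404). In mutants they had 45 and 35 (permutation p 0.00694, adjusted p 0.104). Neither passed.

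No region of any antibody lay within 50 kb of the Y chromosome genes Kdm5d, Eif2s3y, Uty and Ddx3y. H3K4me2 lists held 3, 1, 2 and 2 peaks on chromosome Y in the 4 control libraries and 0 in each of the 4 mutant libraries. The AR and FOXA1 lists of both genotypes held none. Counts this small, with no region at these genes in controls either, do not show a chromosome Y that mutants lack.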
